A study of Mus musculus with 76 samples.

How the data were processed

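RNA was measured by sequencing in neural cultures grown from mouse embryonic stem cells of 2 inbred strains, C57BL/6J (B6) and WSB/EiJ (WSB). Per the labels' protocols, libraries were made from polyadenylated RNA with a stranded kit. The deposited table held 76 sequenced samples and 38924 genes. Its values were expected counts, as the authors' processing notes name RSEM: non-negative numbers of which 9.318% were not whole, with no scaling between samples. Per the submitters' processing notes the tools were Bowtie2, RSEM, featureCounts and limma on the mouse build GRCm38, with no versions, settings or annotation release given. How reads that map to several genes were shared out is not stated beyond the name of RSEM, which divides such reads between the genes by estimated abundance. Of the gene identifiers, 37607 carried a symbol in the reference annotation of the same build and 1317 did not, and these 1317 held 0.2652% of the counts.

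The culture names in the labels showed that 6 libraries had been sequenced in more than 1 run. Their runs were summed, and sums were rounded to whole numbers, which left 70 libraries in 16 groups. The chi-square per degree of freedom between repeat runs was 2.299 to 2.397, against 8.56 to 807.66 for 126 pairs of replicate libraries, so no replicate pair behaved like 1 library sequenced again. Groups were defined by stage, strain, treatment and, at the axon stage, axotomy, all from the labels. Library totals ran from 20.37 to 131.5, in units of 1e6 expected counts, with 18643 to 21389 genes detected. PCR reads without molecular identifiers are not independent molecules, so counts measure depth but not molecules.

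Each stage was fitted on its own, with all of its groups sharing 1 estimate of the spread. Counts were scaled with TMM factors, filtered with filterByExpr, and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. They measure the spread between libraries, not between donors or mice. The library block of the labels entered the fits of the NPC and axon stages, and maturation had 1 block. Errors after ± are standard errors for log2 differences and standard deviations for levels, in counts per 1e6 (CPM) of TMM-scaled totals. Adjusted p-values without a named tool are from edgeR. The maturation and NPC stages came from different library blocks, so the comparison of stages cannot be separated from library preparation.

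The rule for named genes, the gene lists and the first set of alternatives were all chosen before the data were examined. The genes named for each comparison were, among called genes with a mean log2 CPM of at least 1 and a symbol that was not a placeholder, the 12 with the smallest p at 2-fold or more in each direction. To these came up to 4 members with the smallest p of each described list, and Dyrk1a, the target of the compound. Not every gene that the rule takes is printed. The 40 gene lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, and again with a correlation estimated from the data. The estimated correlation is noisy with few libraries, and the test with it called no list in any comparison as planned.

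DESeq2 1.42.0, RLE size factors, no filter, first runs only, other library blocks, and leaving out each replicate at maturation and at the axon stage were that first set of alternatives. Groups of the NPC stage had 6 libraries, and none of these was left out in turn. The alternatives that follow were chosen after seeing the data. Culture names in the labels gave 2 culture experiments at maturation, 4 culture sets per strain at the axon stage, and 3 per strain in the second library block of the NPC stage. Whether these names pair libraries was checked from the correlation of deviations from group means, before calls were compared. At the axon stage all 21 pairs of 1 set in B6 correlated above 0.1, with a lowest value of 0.701. In WSB 19 of 21 did, and 19 of 19, with a lowest value of 0.648, once the library labelled axon WSB ID-8 cut replicate 3 was left out. At maturation 40 of 48 pairs of 1 experiment correlated above 0.1, with a lowest value of -0.248. In the second library block of the NPC stage 3 of 3 pairs of 1 set did in B6 (lowest 0.148) and 2 of 3 in WSB (lowest 0.032). In the first library block, paired by replicate number, 2 of 3 pairs did in B6 (lowest 0.068) and 3 of 3 in WSB (lowest 0.326), and 13 of 18 over all 4 groups. Culture sets therefore pair the axon libraries and the B6 libraries of the second library block of the NPC stage. Replicate numbers pair control with ID-8 libraries of WSB in the first library block of the NPC stage. Fits with the axon set as a block, with and without the library named above, are given beside the results they change. The culture experiments did not pair every library at maturation, nor the culture sets in WSB at the NPC stage. Because the labels name the cultures, blocked counts are given at maturation, and at the NPC stage for the difference between the strains' responses to ID-8 only. That blocked count also uses the WSB sets, which did not pair every library. The counts for ID-8 in B6 at the NPC stage do not use the pairing by culture set found there. At maturation, replicate libraries of 1 experiment had a median chi-square per degree of freedom of 30.505, against 141.205 for those of different experiments. The 4 libraries of a maturation group are thus not 4 independent cultures. Fits of 1 experiment alone measure only the spread within that experiment. All fits at maturation, also those with the experiment as a block, count the libraries of 1 experiment as separate replicates. Their p-values and standard errors thus rest in part on the spread within experiments.

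Shared sequence between genes was measured from the transcripts of GENCODE on the same build, as the share of 31-mers, sampled at 1 in 16, that also occur in another gene. Genes with at most 1% shared, a symbol and no pseudogene annotation are called genes without shared sequence. The fits of ID-8 in B6 at each stage and of axotomy in B6, and no others, were tested on simulated data with 50 genes changed at each fold size. For ID-8 in B6, 2-fold changes were recovered for 66% of changed genes at the NPC stage, 50% at maturation and 50% at the axon stage. With culture sets as a block the last value was 70%. For axotomy in B6 the shares at 2-fold were 44% with library blocks and 74% with culture sets. Wrong calls, of genes not changed, were counted in the same data. For ID-8 in B6 they were 11 of 155 in edgeR and 26 of 184 in DESeq2 at the NPC stage. At maturation they were 3 of 116 and 30 of 163, and at the axon stage 2 of 111 and 25 of 150. With culture sets the last values were 12 of 160 and 21 of 176. For axotomy in B6 they were 5 of 107 and 17 of 128, and 7 of 153 and 20 of 171 with culture sets.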

Results

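RNA was sequenced from neural cultures grown from embryonic stem cells of 2 mouse strains, the standard strain C57BL/6J (B6) and the wild-derived strain WSB/EiJ (WSB). Cells were collected at 3 stages, namely differentiation of neural progenitor cells (NPC), maturation of neurons, and a stage of axonal regrowth (axon). Each library holds RNA of a whole culture. At maturation Map2 of the pan-neuronal list had a mean log2 CPM of 9.68. Gfap of the astrocyte list read 10.95 and Col1a1 of the fibroblast list 8.5. The neurons and progenitors named below are thus whole cultures, and changes of cell composition were not tested. Part of the cultures received ID-8, an inhibitor of the kinase DYRK1A, and at the axon stage part had their axons severed (cut) while the others were left uncut. The design asks how the strains differ, how ID-8 acts in each, and how neurons respond to axotomy. The NPC stage had 24 libraries, 6 in each of 4 groups. Maturation had 16 libraries, 4 in each of 4 groups. The axon stage had 30 libraries, 4 in each of 8 groups except WSB ID-8 uncut and B6 ID-8 cut with 3. Library totals, in units of 1e6 expected counts, were 22.88 to 131.5 at the NPC stage (median 52.4), 25.12 to 41.74 at maturation (median 30.88) and 20.37 to 99.19 at the axon stage (median 35.64).

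**Figure D1:**
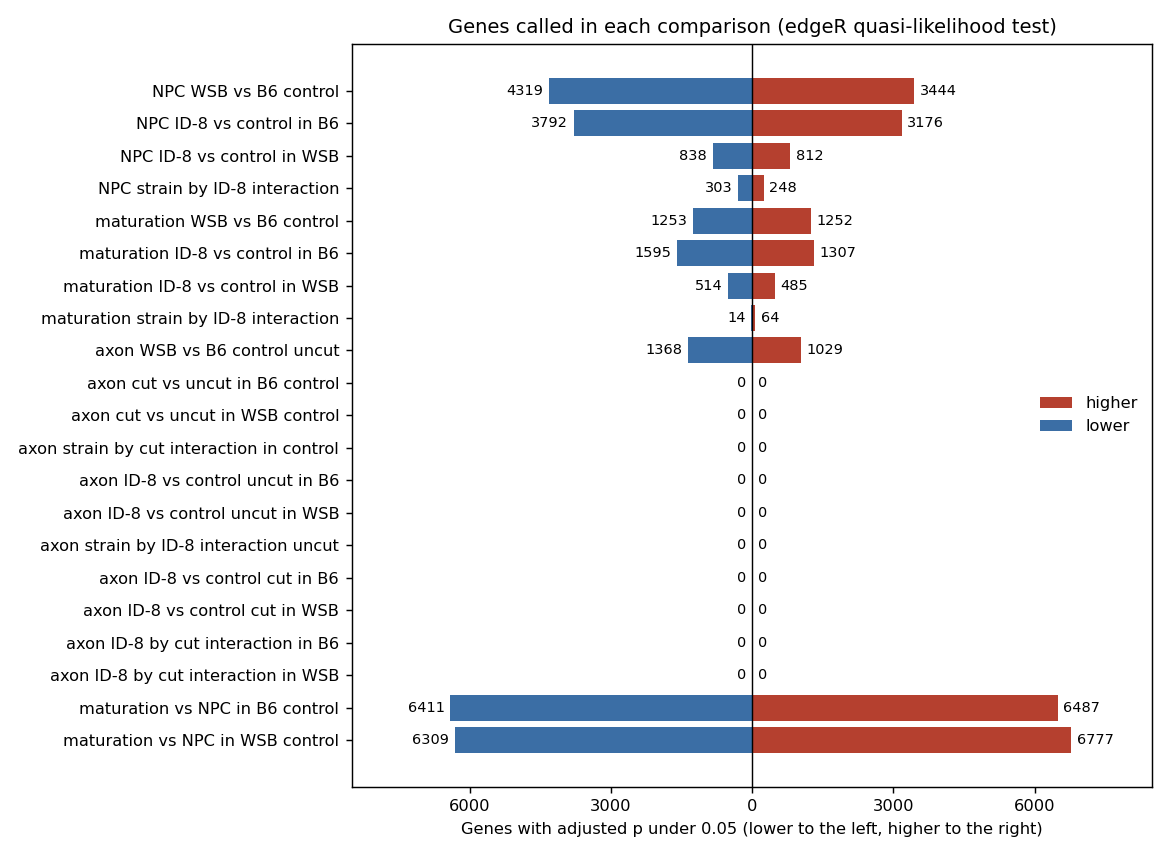
Number of genes called in each comparison, with higher genes to the right and lower genes to the left of 0 on a linear axis. Strain gave 7763 calls at the NPC stage, and 10 of the 11 axon comparisons called 0 genes in the fit with library blocks.

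Dyrk1a, which encodes the target of ID-8, was expressed in all groups at a mean of 90.39 to 137.7 CPM. Its transcript fell by 0.29 ± 0.07 on the log2 scale with ID-8 in B6 at the NPC stage (adjusted p = 0.00224), from 134.9 ± 12.4 to 110.5 ± 12.4 CPM (SD, n = 6). The change in WSB was -0.06 ± 0.07 (adjusted p = 0.683), and the difference between the strains' responses was 0.24 ± 0.10 (adjusted p = 0.159). Dyrk1a was not called with ID-8 at maturation or at the axon stage, with library or culture blocks. Dyrk1a was also lower at maturation than at the NPC stage in WSB (-0.57 ± 0.11, adjusted p = 9.01e-05). In control neurons at maturation it read 124.4 ± 12.5 CPM in B6 and 90.39 ± 10.1 in WSB (n = 4), a difference of -0.46 ± 0.17 (adjusted p = 0.0787), which was called with the culture experiment as a block (-0.46 ± 0.13, adjusted p = 0.0181).

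The strains differed widely as neural progenitors. In WSB 15 of 15 pluripotency genes were lower, while 8 of 18 synaptic genes were higher, and 12 of 16 of cholesterol synthesis were higher and 1 lower. With an estimated correlation none of these 3 list calls held (adjusted p = 0.781 for each). The most significant differences, however, lay in abundant genes and their pseudogene copies, where reads can be assigned to either. Of 17248 genes tested in control NPC cultures, 3444 were higher and 4319 lower in WSB. Within the first library block alone 4213 genes were called, and 2794 within the second. The nuclear import receptor Kpna2 (ENSMUSG00000018362, chromosome 11, 106988629 to 106999541) read 336.9 ± 47.8 CPM in B6 and 5.65 ± 0.90 in WSB (SD, n = 6), a log2 difference of -5.90 ± 0.11 (adjusted p = 3.4e-21). The ribosomal protein genes Rpl29, Rps2, Rps3a1 and Rpl35a, the methyl-cycle enzyme Ahcy, Ptma, Eif3j1, Tdg, Ncoa4 and Zfp738 were lower as well, by -2.41 (Eif3j1) to -7.16 (Rps2) on the log2 scale. Conversely Ftl1-ps1 read 0.62 ± 0.24 CPM in B6 and 844.4 ± 86.7 in WSB, and Rpl3-ps2, Rps24-ps3, Rps26-ps1, Rps3a2, Gapdh-ps15, Atp6v0c-ps2, Tpm3-rs7, Rps3a3, Hmga1b and Tcea1-ps1 were higher in WSB too. Of the 12 genes with the smallest p on the higher side, 11 shared more than 70% of their sampled transcript sequence with other genes, and only Wdfy1, at 3.29 ± 0.12 (adjusted p = 4.5e-16), shared about 1%. Per library total, without TMM factors, Kpna2 alone read 348.9 ± 45 CPM in B6 and 5.62 ± 0.81 in WSB, and summed over the 9 genes that share its sequence 349.9 ± 45 and 343.5 ± 49.4. On the same scale the glycolytic gene Gapdh, chosen after its values were seen, read 3254 ± 477 CPM in B6 and 175.5 ± 49.1 in WSB alone, but 3610 ± 539 and 3486 ± 359 summed over 38 genes. Other sums did not all match. Summed, Ptma read 1668 ± 88 CPM in B6 and 1062 ± 100 in WSB, Rps2 1672 ± 376 and 1157 ± 184, and Ahcy 230 ± 41 and 153 ± 29. Summed Rpl29 read 405 ± 71 and 341 ± 37, and summed Tdg was higher in WSB, at 217 ± 21 and 305 ± 23. The values of single genes with shared sequence are therefore uncertain.

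**Figure D2:**
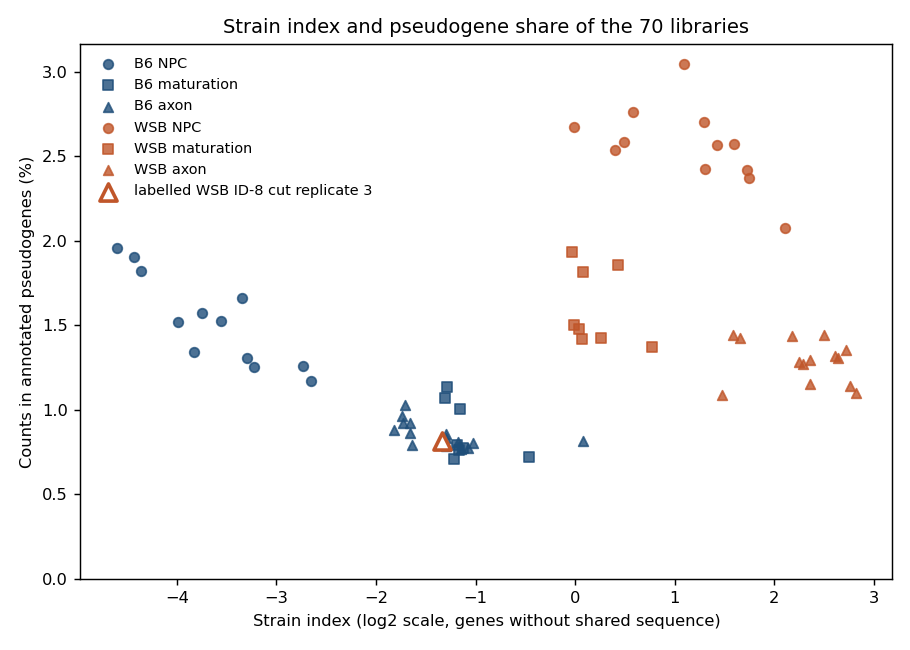
Share of counts in annotated pseudogenes against a strain index, the log2 level of 1 gene higher in WSB less the mean log2 level of 90 genes lower in WSB, for the 70 libraries. These genes, without shared sequence, were picked as called and at least 8-fold apart between the control libraries of the strains at the NPC stage. The separation of those libraries was therefore fixed in advance. B6 and WSB libraries lay apart at each stage, and 1 library labelled WSB, drawn as a large open triangle, lay among B6 libraries at -1.333.

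Among 10490 genes without shared sequence, tested after the data had been seen, 2080 were higher and 2508 lower in WSB progenitors. Hemk1, which methylates translation release factors, rose from 5.17 ± 1.04 CPM in B6 to 17.5 ± 2.02 in WSB (SD, n = 6; log2 1.76 ± 0.13, adjusted p = 3.99e-09). Efcab7 and Cfap69, both tied to cilia, the receptors Gpr182 and Hrh3, the glycine transporter Slc6a9, Ssbp4, the cytokines Ccl25 and Il17d, Mypop, the glycogen enzyme Gbe1 and the lipogenic regulator Mid1ip1 followed, at log2 differences of 1.09 (Mid1ip1) to 2.64 (Hrh3). The genes with the smallest p downward included the aldo-keto reductase Akr1e1 (-3.79 ± 0.22, adjusted p = 2.08e-10), the protease Capn11 (-7.98 ± 0.48), the ATP synthase subunit Atp5e (-3.66 ± 0.22), Aard, the lipid transfer gene Gltp, Rinl, the stem cell noncoding RNA Lncenc1 (-4.09 ± 0.30), Clgn, the pluripotency-linked factor Tbx3 (-3.32 ± 0.27) and the polycomb partner Phf19. The gene lists were tested over all genes, with or without shared sequence. Of 15 pluripotency genes fixed in advance, 15 were lower in WSB and 15 adjusted over the list alone, with a median of -3.86 (camera, adjusted p = 1.68e-11, and adjusted p = 0.781 with an estimated correlation). The stem cell factor Nanog (chromosome 6, 122707489 to 122714633) read 104.3 ± 51.8 CPM in B6 and 4.03 ± 1.47 in WSB (-4.70, adjusted p = 2.83e-09). Dppa3 (-4.04), Dppa5a (-3.63) and Utf1 (-3.86) were also lower. Synaptic genes leaned the other way, with 8 of 18 higher and 8 adjusted over the list alone, among them Camk2a (0.94), Homer1 (0.59), Cplx1 (1.70) and Dlg4 (1.14) (camera, adjusted p = 0.00337, and 0.781 with an estimated correlation). Cholesterol synthesis had 12 of 16 higher and 1 lower, 12 and 1 adjusted over the list alone, led by Sqle (0.61), Msmo1 and Hmgcs1 (0.99) (camera, adjusted p = 0.0012, and 0.781 with an estimated correlation). Of 13 interferon response genes 8 were lower and 1 higher, 8 and 1 adjusted over the list alone, with Ifih1 (-2.57), Rsad2 (-3.70), Oasl2 (-2.41) and Irf7 (-2.90) in front (camera, adjusted p = 0.0314, and 0.781 with an estimated correlation). Nanog, Dppa3, Dppa5a, Camk2a, Dlg4, Msmo1 and Hmgcs1 were not among the genes without shared sequence. Among those genes, 5 of 5 pluripotency genes were lower, 5 of 15 synaptic genes higher, 4 of 6 cholesterol synthesis genes higher and 1 lower, and 5 of 7 interferon response genes lower and 1 higher, and the same numbers adjusted over each list alone (camera, adjusted p = 0.000214, 0.0225, 0.132 and 0.0656, and 0.481, 0.773, 0.772 and 0.772 with an estimated correlation).

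In B6 progenitors with ID-8, most genes tested in the lists of endoderm, mesenchyme, matrix, the integrated stress response and the cell cycle were higher, and most in the synaptic and pan-neuronal lists were lower. None of these list calls held with an estimated correlation (adjusted p = 0.572 for the first 4 lists, and 0.663, 0.592 and 0.739 for cell cycle, synaptic and pan-neuronal). The test called 3176 genes higher and 3792 lower. The first library block alone gave 1379 genes, or 2010 with replicate numbers as a block, and the second gave 3880. The polyamine enzyme Srm rose from 49.0 ± 9.69 to 107.1 ± 16.8 CPM (SD, n = 6; log2 1.14 ± 0.10, adjusted p = 3.36e-07). Gas6, a ligand of receptor kinases, rose by 2.17 ± 0.20 and the hyaluronan-degrading gene Cemip by 4.29 ± 0.39 (adjusted p = 3.69e-07 for each). The activin antagonist Fst (3.31), Npl (4.00), Ptx3 (3.27), Slc1a4, Akr1b3, Bex4 and the DNA damage gene Gadd45a rose as well. Slc18a2, which loads monoamines into vesicles, fell from 25 ± 3.02 to 5.51 ± 0.70 CPM (-2.19 ± 0.20, adjusted p = 3.69e-07). The linker histone H1f0 (-1.04), Arid3a (-1.39), Med12l, Osbp2, Adgrg1, Taf9b, Olr1 (-4.15), the ventral neural tube factor Nkx6-1 (-4.82), Sorcs2, Ebf4 and Shisal1 (-2.21) also fell. Of 9 endoderm and liver genes 8 rose and 8 adjusted over the list alone, with Gata6 (3.90), Gata4 (4.20), Ttr (7.07) and Sox17 (3.93) in front (camera, adjusted p = 1.33e-05, and 0.572 with an estimated correlation). Gata4 read 4.56 ± 1.92 CPM in control and 82.5 ± 52.5 with ID-8. Extracellular matrix genes had 11 of 14 higher and 1 lower, 11 and 1 adjusted over the list alone, such as Lama1 (2.88), Sparc (2.35) and Tnc (3.48), with Vcan lower (-1.81) (camera, adjusted p = 8.43e-05, and 0.572 with an estimated correlation). The integrated stress response, which reprogrammes translation, had 10 of 15 higher, 10 adjusted over the list alone, led by Chac1 (1.73), Atf4 (0.66), Phgdh (0.66) and Shmt2 (0.74) (camera, adjusted p = 0.000121, and 0.572 with an estimated correlation). Mesenchyme genes had 10 of 13 higher, 10 adjusted over the list alone, with Prrx1 (3.24), Acta2 (3.36) and Thy1 (2.02) first (camera, adjusted p = 0.000365, and 0.572 with an estimated correlation). Pan-neuronal genes had 10 of 16 lower, 11 adjusted over the list alone, with Mapt (-1.34) and Elavl3 (-1.02) first (camera, adjusted p = 0.00388, and 0.739 with an estimated correlation). Synaptic genes had 14 of 18 lower, 15 adjusted over the list alone, led by Camk2a (-1.06), Dlg4 (-1.48), Sv2a (-1.23) and Syn2 (-1.11) (camera, adjusted p = 3.36e-05, and 0.592 with an estimated correlation). The cell cycle list had 15 of 24 higher and 16 adjusted over the list alone, with Ccne1 (0.77) first (camera, adjusted p = 0.000565, and 0.663 with an estimated correlation).

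In WSB progenitors 12 of 15 pluripotency genes were higher with ID-8 (adjusted p = 0.506 for the list with an estimated correlation), and Tpbpa was lower. The count of calls was smaller than in B6, at 812 higher and 838 lower. The first library block alone gave 166 genes, or 284 with replicate numbers as a block, and the second gave 2. The signalling inhibitor Spry2 rose from 18.9 ± 2.33 to 40.7 ± 7.84 CPM (SD, n = 6; log2 1.11 ± 0.14, adjusted p = 0.000102). Zfp819, the kinase Syk, Hoxa10 (5.74), Sept1, the arginine transporter Slc7a3, Ooep (3.01), Cbs (2.17), the threonine enzyme Tdh (3.72) and the germline factor Prdm14 (2.78) rose too. H1f0 fell from 411.7 ± 26.6 to 198.5 ± 30.2 CPM (-1.05 ± 0.09, adjusted p = 2.02e-06), a change of the same size as in B6. Tpbpa (-6.61 ± 0.76), Ctsr (-4.98 ± 0.61), Ctsq (-5.81 ± 0.76), Prl7d1 (-4.22) and Ctsj (-4.18) fell, and Tpbpa dropped from 10.7 ± 5.88 to 0.12 ± 0.03 CPM. Camk2a (-1.41), Syt17 (-1.60), Olr1 (-3.42), Slc18a2 (-1.47), Pacsin1 (-1.24) and the leptin receptor Lepr (-3.21) fell. Of 15 pluripotency genes 12 rose, 13 adjusted over the list alone, with Pou5f1 (2.74), Utf1 (2.44) and Tdgf1 (2.88) beside Tdh (camera, adjusted p = 7.54e-14, and 0.506 with an estimated correlation). Cell cycle genes leaned the same way, with 6 of 24 higher and 8 adjusted over the list alone, led by E2f1 (0.78) (camera, adjusted p = 0.00379, and 0.874 with an estimated correlation).

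A test of the difference between the strains' responses asks where ID-8 acted differently. It called 248 genes with a more positive response in WSB and 303 with a more negative one. With culture sets, which did not pair every WSB library, as a block it called 1083 and 665. The first library block alone gave 0 genes in edgeR (1292 at an unadjusted p under 0.05, and 1 with replicate numbers as a block) and so did the second (2526 at an unadjusted p under 0.05), while DESeq2 on both blocks called 1251. The response was more positive in WSB for 4 of 17 neural progenitor genes, and more negative for 2 of 9 endoderm and 2 of 13 mesenchyme genes, and none of these 3 list calls held with an estimated correlation (adjusted p = 0.566, 0.562 and 0.562). The patterning factor Irx3 fell from 65.6 ± 22.5 to 29.1 ± 15.2 CPM with ID-8 in B6 and read 86.7 ± 22.6 and 123.7 ± 40.6 in WSB (difference of log2 responses 1.69 ± 0.28, adjusted p = 0.00491). Nkx6-1 (3.49 ± 0.61), the Notch target Hes5 (2.66 ± 0.49), Hs3st3b1 (1.43), Hs3st3a1 (1.85), Irx3os (1.83), Lrig1 (1.34), Igdcc3, Stk33, Fam78b, Fignl2 and Jazf1 differed the same way. Gas6 (-2.38 ± 0.27, adjusted p = 0.000168), Ptx3 (-2.88), the zinc transporter Slc39a8, Hal, Wnt11 (-3.36), Foxd3, Cemip (-3.17), the collagen gene Col3a1 (-2.29), Pdlim4, Myo6, Bicc1 and Mtmr11 responded more in B6. Of 9 endoderm and liver genes 2 differed, 2 adjusted over the list alone, namely Gata4 (-3.97) and Gata6 (-3.29) (camera, adjusted p = 3.08e-05, and 0.562 with an estimated correlation). Of 13 mesenchyme genes 2 differed, 7 adjusted over the list alone (camera, adjusted p = 3.43e-06, and 0.562 with an estimated correlation). Of 17 neural progenitor genes 4 differed, 5 adjusted over the list alone, with Prom1 (0.98), Sox3 (1.65) and Pax6 beside Hes5 (camera, adjusted p = 0.00155, and 0.566 with an estimated correlation).

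As mature neurons the strains again differed, with the serine carboxypeptidase gene Scpep1 lower in WSB. There 6 of 13 fibroblast genes were higher and 8 of 15 genes of the integrated stress response lower (adjusted p = 0.981 for each list with an estimated correlation). In control cultures 1252 genes were higher and 1253 lower in WSB. With the culture experiment as a block 2343 were higher and 2265 lower. Each experiment on its own, with 2 libraries per group, gave 4821 and 4998 calls, which measure only the spread within that experiment. Pseudogenes and other genes that share sequence again led the list, with Rpl3-ps2, Rpl3-ps1, Tpm3-rs7, Rps2-ps13, Atp6v0c-ps2, Eno1b and Rps26-ps1 higher and Tdg (-3.49 ± 0.13), Gapdh (-5.39 ± 0.22), Rps2 (-6.51 ± 0.28), Kpna2 (-5.21 ± 0.25), Ptma and Ahcy lower. Cwc22, not a pseudogene and with 21.5% of its sequence shared, was also higher (4.72 ± 0.21). Per library total, Gapdh summed over its 38 genes read 1874 ± 48.3 CPM in B6 and 2086 ± 467 in WSB (SD, n = 4), against 1775 ± 42.2 and 42.5 ± 7.45 alone. Summed Ptma (536.2 CPM in B6 and 279.1 in WSB), Ahcy (72.4 and 53.9), Tdg (50.84 and 42.65) and Rpl29 (180.8 and 166.6) stayed lower in WSB. Summed Rps2 (645.6 and 761.2) and Kpna2 (43.8 and 53.9) read higher there. Of 10443 genes without shared sequence 718 were higher and 627 lower. Scpep1 read 454.4 ± 60.6 CPM in B6 and 76.6 ± 14.4 in WSB (-2.57 ± 0.18, adjusted p = 1.02e-06). Ccl28 (-4.02), Akr1e1 (-2.56), Capn11 (-4.62), Mpzl3, Samd12 (-7.05), Elovl7, Ahnak2, Adgrg2, Onecut2 and Hoxb9 (-2.18) were lower. Abhd1 (3.97 ± 0.30, adjusted p = 1.55e-06), the retinoid receptor Rxrg (1.92), the laminin Lama3 (2.35), Dmrtb1, Efcc1, the retinal transporter Abca4, Efcab7 (1.69), Lcat (2.20), Got1l1, Scrg1 and Tfpi were higher. Fibroblast genes had 6 of 13 higher, 7 adjusted over the list alone, with Col1a2 (3.18), Lum (1.96), Col1a1 (2.35) and Postn (1.68) in front (camera, adjusted p = 0.0198, and 0.981 with an estimated correlation). The stress response list had 8 of 15 lower, 9 adjusted over the list alone, with Cebpb (-1.76), Asns (-0.90), Chac1 (-1.40) and Mthfd2 (-1.18) first (camera, adjusted p = 0.00369, and 0.981 with an estimated correlation).

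In mature B6 neurons with ID-8, 10 of 14 interferon response genes and 4 of 6 epithelial genes were lower, and 4 of 8 genes of the oligodendrocyte lineage were higher. None of these list calls held with an estimated correlation (adjusted p = 0.555, 0.448 and 0.448). The test called 1307 genes higher and 1595 lower. With the culture experiment as a block the counts were 2270 and 2553, and each experiment alone gave 5414 and 5068 calls. The growth factor Ptn (chromosome 6, 36714929 to 36810220) rose from 14.8 ± 2.71 to 103 ± 9.61 CPM (SD, n = 4; log2 2.80 ± 0.16, adjusted p = 1.88e-07). The BMP antagonist Grem1 (2.15 ± 0.16), the oligodendrocyte factor Olig2 (4.25 ± 0.35), the GDNF-family receptor Gfra2 (2.65), Fjx1 (2.29), St8sia5, the sulfotransferase Chst2 (3.02), the glial connexin Gjc3 (4.41), Elovl7, Tubb2b (2.01), the proteoglycan Bcan (2.69) and Cmtm5 (2.70) rose. The complement regulator Cd59a fell from 34.8 ± 9.25 to 1.81 ± 0.38 CPM (-4.26 ± 0.27, adjusted p = 2.3e-07). Zfp185 (-2.77 ± 0.17), C1qtnf3 (-3.31), the laminin Lama5 (-2.60), the folate receptor Folr1 (-4.91), Calml4 (-3.22), Igf2bp1 (-3.54), the collagen Col4a3 (-3.42), Gstt1, Sult1a1 (-3.88) and Pdia4 (-1.44) fell. Of 14 interferon response genes 10 fell, while 10 fell and 1 rose adjusted over the list alone, with Ifi44 (-3.76), Irf7 (-3.16), Ifih1 (-1.82) and Ifit3 (-1.45) first (camera, adjusted p = 0.00015, and 0.555 with an estimated correlation). Of 8 oligodendrocyte genes 4 rose, 4 adjusted over the list alone, with Olig1 (2.05) and Mbp (0.88) beside Olig2 (camera, adjusted p = 0.00445, and 0.448 with an estimated correlation). Of 10 astrocyte genes 3 rose, 3 adjusted over the list alone, namely S100b (1.95), Sparcl1 (1.95) and Slc1a2 (1.94) (camera, adjusted p = 0.00811, and 0.803 with an estimated correlation). Matrix genes had 4 of 14 lower and 1 higher, 9 lower and 1 higher adjusted over the list alone, with Ccn1 (-2.89) and Thbs1 (-1.77) among them (camera, adjusted p = 0.00484, and 0.803 with an estimated correlation). Epithelial genes had 4 of 6 lower, 4 adjusted over the list alone, namely Cdh1 (-2.38), Krt19 (-2.73), Krt18 (-2.94) and Krt8 (-3.10) (camera, adjusted p = 0.0104, and 0.448 with an estimated correlation).

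In mature WSB neurons with ID-8, 379 genes were lower that were lower in B6 too, against 48.4 for independent lists. Of 14 interferon response genes 5 were higher (adjusted p = 0.75 for the list with an estimated correlation). The test called 485 genes higher and 514 lower. With the culture experiment as a block the counts were 1215 and 1192, and each experiment alone gave 2329 and 2625 calls. The count fell to 511 without WSB control replicate 1, 577 without WSB control replicate 2, 639 without WSB control replicate 3, 623 without WSB ID-8 replicate 2 and 565 without WSB ID-8 replicate 4, and DESeq2 called 1772. The cytokine Il17b (chromosome 18, 61684887 to 61692538) rose from 2.42 ± 0.58 to 74.5 ± 24.4 CPM (SD, n = 4; log2 4.94 ± 0.33, adjusted p = 2.23e-06). Hopx (2.19), Tubb2b (1.64), Aldh1a7 (3.93), Atp13a4 (3.05), Chst2 (2.28), Olig2 (2.86 ± 0.33), Shc4, Akain1, the phosphatase Dusp4 (1.95), the chemokine Ccl5 (7.25 ± 0.92) and the hyaluronan synthase Has2 (3.81) rose. Zfp185 fell by 2.13 ± 0.17 (adjusted p = 1.12e-05), from 8.40 ± 0.66 to 1.91 ± 0.21 CPM. Folr1 (-4.01), C1qtnf3 (-2.14), Vtn (-1.98), Got1l1, Calml4 (-2.10), Sult1a1 (-2.64), Akr1c14, Col8a2 (-2.47), Col4a3 (-2.21) and Tlr4 (-1.75) fell as well. Interferon response genes had 5 of 14 higher, 7 adjusted over the list alone, with Rsad2 (2.67), Ifit1 (2.32), Ifit3 (1.18) and Oasl2 (1.43) first (camera, adjusted p = 1.9e-05, and 0.75 with an estimated correlation).

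In the test of how the strains' responses to ID-8 differed in mature neurons, the interferon response had the smallest p of the gene lists, with 5 of 14 genes called (adjusted p = 0.0708 with an estimated correlation). The test of that difference called 64 genes with a more positive response in WSB and 14 with a more negative one. The count was 323 with the culture experiment as a block, 484 and 611 in each experiment alone, and 327 in DESeq2. Leaving out 1 library moved it to 40 without WSB control replicate 3, 44 without B6 control replicate 4, 45 without WSB ID-8 replicate 2, 46 without WSB control replicate 4, 50 without B6 ID-8 replicate 4, and 142 without WSB ID-8 replicate 3. Ifi44 (chromosome 3, 151730922 to 151749960) fell from 9.88 ± 4.6 to 0.72 ± 0.07 CPM in B6 and read 8.01 ± 3.94 and 19.8 ± 7.12 in WSB (SD, n = 4; difference 5.07 ± 0.57, adjusted p = 0.00115). Of 14 interferon response genes 5 were called, 12 adjusted over the list alone, and the median difference was 2.54, with Ifit3 (2.63), Oasl2 (2.87) and Irf9 (1.32) beside Ifi44 (camera, adjusted p = 2.46e-21, and adjusted p = 0.0708 with an estimated correlation). With the culture experiment as a block, 12 were called and the estimated correlation gave an adjusted p of 0.0298. That fit still counts the libraries of 1 experiment as separate, so these values rest in part on the spread within experiments. The list's mean log2(CPM + 1) was 3.68 ± 0.30 in B6 control and 2.56 ± 0.08 in B6 with ID-8, against 3.69 ± 0.58 and 4.55 ± 0.50 in WSB. Cd59a (3.13 ± 0.34), Crym (2.93), Il17b (3.76), Ahnak2 (1.67), Lama5 (1.82), Gbp9 (2.35), Pgm5 (3.76), Scpep1 (1.65), Trim5 (3.31) and Lmod1 (3.20) also differed upward in WSB. Ptn (-1.88 ± 0.21, adjusted p = 0.00115), Grem1 (-1.69), Pcsk6 (-1.29), Fjx1 (-1.57), Gjc3 (-2.78), Efcc1 (-1.37), Ddit4l (-1.58), Ntsr2 (-1.87), Dkk2 (-2.61) and Vhl (-0.86) responded less in WSB.

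**Figure D3:**
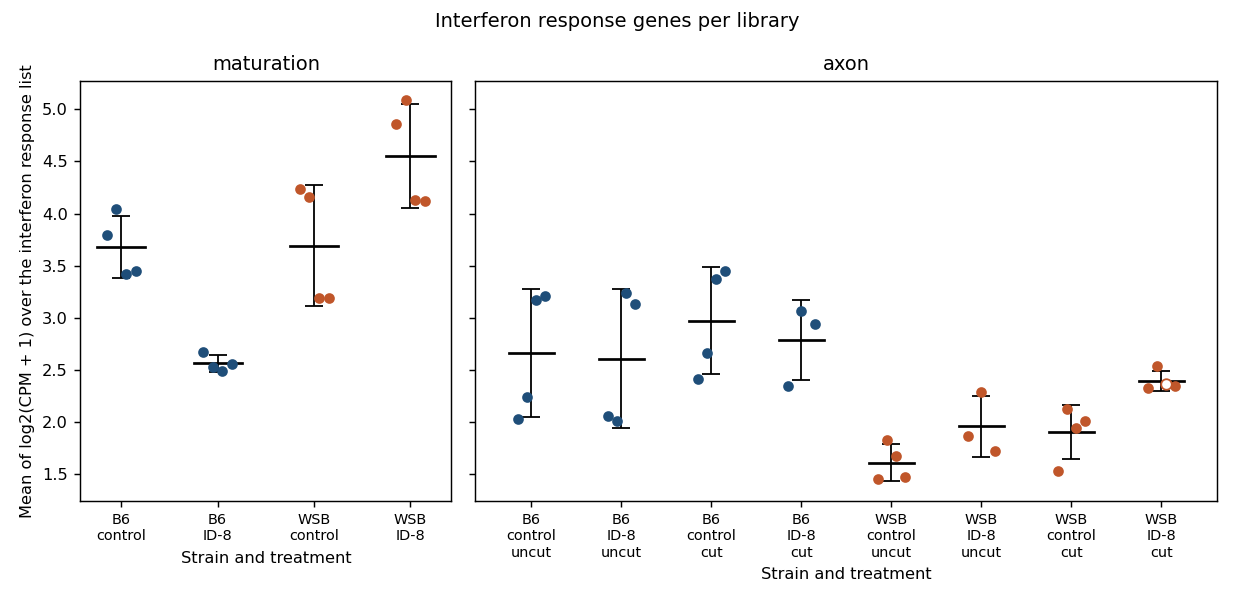
Mean log2(CPM + 1) over the interferon response genes in each library of the maturation and axon stages, with points for libraries, horizontal lines for group means and bars for the SD. At maturation ID-8 went with lower values in B6 and higher values in WSB, and the open point is the library labelled axon WSB ID-8 cut replicate 3.

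At the axon stage 9 of 14 interferon response genes, 5 of 8 epithelial genes and 4 of 6 endothelial genes were lower in uncut control neurons of WSB, and 4 of 10 astrocyte genes were higher. None of these list calls held with an estimated correlation (adjusted p = 0.406 for each). The test called 1029 genes higher and 1368 lower in WSB. The count fell to 1518 without WSB control uncut replicate 2 and 1404 without WSB control uncut replicate 3, and it was 1590 with no library block term. Wdfy1 read 15.1 ± 0.87 CPM in B6 and 113.9 ± 6.87 in WSB (SD, n = 4; log2 2.94 ± 0.30, adjusted p = 1.83e-05). Tpm3-rs7 (7.40), Hddc3 (2.93), the monoamine oxidase Maoa (1.35), Rps15a-ps7, Rps3a2, Rpl3-ps2, Itih3 (3.82), Cwc22 (4.14), Amd2, the signal Wnt7b (1.79) and Rps26-ps1 were higher, of which the pseudogenes, Tpm3-rs7 and Amd2 shared most of their sequence with other genes. The hedgehog-binding gene Hhip read 17.1 ± 2.17 CPM in B6 and 7.59 ± 3.86 in WSB (-1.60 ± 0.21, adjusted p = 3.52e-05). Tmem254b, Tmem254a, Sytl2 (-2.35), Tpm3 (-1.69), H2-T24 (-5.72), Rsph3a, Atp5e (-3.58), Polr2l, Fam43a, Tmem267 and Tdg (-3.05) were lower. Among 11081 genes without shared sequence 514 were higher, with Smoc1 (1.61), Chst3 (1.98), Fgf1 (1.86), Clec3b (2.55) and Ptprz1 (1.66) after Itih3 and Wnt7b, and 763 lower, with the chemokine Cxcl10 (-4.32), Foxf1 (-2.22), the nicotinic receptor gene Chrna3 (-1.97) and Cdkn2a (-1.94) among them. Astrocyte genes had 4 of 10 higher, 6 adjusted over the list alone, namely Sparcl1 (2.29), Fgfr3 (1.54), Slc1a3 (1.41) and Aldoc (1.11) (camera, adjusted p = 0.000111, and 0.406 with an estimated correlation). Interferon response genes had 9 of 14 lower, while 10 were lower and 1 higher adjusted over the list alone, with Oasl2 (-3.56), Ifit1 (-3.79), Bst2 (-2.88) and Rsad2 (-2.17) first (camera, adjusted p = 3.93e-06, and 0.406 with an estimated correlation). Epithelial genes had 5 of 8 lower, 6 adjusted over the list alone, with Krt8 (-5.16), Krt18 (-4.83), Krt19 (-5.13) and Cdh1 (-3.25) first (camera, adjusted p = 0.000111, and 0.406 with an estimated correlation). The p53 targets had 8 of 13 lower, 9 adjusted over the list alone, with Zmat3 (-0.67), Phlda3 (-1.29), Bbc3 (-0.97) and Pmaip1 (-2.32) first (camera, adjusted p = 0.000111, and 0.406 with an estimated correlation). Matrix genes had 5 of 14 lower, 10 adjusted over the list alone, with Thbs1 (-2.37) and Lamb1 (-3.42) first, and endothelial genes 4 of 6, 5 adjusted over the list alone, with Pecam1 (-1.52) and Tek (-4.71) first (camera, adjusted p = 0.000182 and 0.00148, and 0.406 for both with an estimated correlation).

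Synaptic and pan-neuronal genes leaned downward after axons were severed, and the number of genes called depended on the fit. None of the calls of these 2 lists held with an estimated correlation (adjusted p = 0.762 for each in WSB, and 0.78 and 0.801 in B6, with library blocks). With library blocks edgeR called 0 genes between cut and uncut controls in B6 (182 at an unadjusted p under 0.05, and 31 called by DESeq2) and 0 in WSB (717 at an unadjusted p under 0.05, and 23 called by DESeq2). Without WSB control cut replicate 1 the WSB count was 2. With culture sets as a block and without the library labelled axon WSB ID-8 cut replicate 3, 1 gene was called in B6, and in WSB 68 were higher and 204 lower. With that library in the fit the count in WSB was 1. Acsl4, which activates polyunsaturated fatty acids, fell by 0.84 ± 0.12 in WSB (adjusted p = 0.0171). Glrb (-0.59), Bcat1 (-0.59), the signalling regulators Rgs8 (-0.71) and Sos2 (-0.41), Ugcg (-0.50), the adhesion genes Cntnap2 (-0.63) and Slitrk4 (-0.69), Napb (-0.52), Gpr176 (-0.70), Trpm2 (-0.93) and Smtnl2 (-1.04) fell too. Lbp (1.40 ± 0.28), Aplnr (1.92 ± 0.44), Tmem252 (1.70), Fmod (1.02), Ccbe1 (1.01), Gas8, the class I light chain B2m (0.57 ± 0.11), Trir, the astrocyte filament Gfap (0.63 ± 0.13), C1ql1 (0.71), Rab32 and Cyb5r3 rose, all with adjusted p-values of 0.0473 to 0.049. Of 18 synaptic genes 3 fell in that fit, 17 adjusted over the list alone, with Snap25 (-0.61) and Sv2a (-0.72) among those past the threshold and Syp (-0.57, adjusted p = 0.0513) short of it (camera, adjusted p = 9.8e-09, and 0.507 with an estimated correlation). Pan-neuronal genes had 1 of 16 lower, 13 adjusted over the list alone, with the neurofilament gene Nefl (-0.53, adjusted p = 0.0476) past the threshold and Mapt (-0.47), Nefm (-0.52) and Elavl4 (-0.42) short of it (camera, adjusted p = 1.91e-07, and 0.507 with an estimated correlation). In B6 the same lists leaned the same way with 0 genes called, at median log2 differences of -0.27 for synaptic and -0.23 for pan-neuronal genes in the fit with library blocks (camera, adjusted p = 4.89e-05 and 0.00325, and 0.78 and 0.801 with an estimated correlation). A test of the difference between the strains called 0 genes in edgeR (137 at an unadjusted p under 0.05, and 36 called by DESeq2).

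ID-8 at the axon stage raised C1ql1 and lowered the complement protease C1ra in both strains when culture sets were the block and the library labelled axon WSB ID-8 cut replicate 3 was left out. C1ra shares 55.49% of its sampled transcript sequence with other genes, so its value as a single gene is uncertain. With library blocks edgeR called 0 genes in each of the 4 comparisons. At an unadjusted p under 0.05 there were 751 in B6 uncut, 1322 in WSB uncut, 675 in B6 cut and 1380 in WSB cut, and DESeq2 called 74, 87, 29 and 121. In simulated data for ID-8 in B6 uncut cultures, 25 of 150 DESeq2 calls were wrong, against 2 of 111 in edgeR with library blocks. Within culture sets, without the library labelled axon WSB ID-8 cut replicate 3, 383 genes rose and 435 fell in B6 uncut, 1018 and 1010 in WSB uncut, 377 and 366 in B6 cut, and 225 and 88 in WSB cut. With that library in the fit the counts were 221, 563, 275 and 357. The library block fit called 1 gene in B6 uncut without the same library, 1 in WSB uncut without WSB control uncut replicate 1, and 1 in B6 cut without B6 control cut replicate 1. In WSB cut it called 7 without WSB ID-8 cut replicate 1, 12 without WSB ID-8 cut replicate 2 and 3 without WSB control cut replicate 3. The interaction of ID-8 with axotomy called 0 genes in edgeR with either block, at 65 in B6 and 742 in WSB at an unadjusted p under 0.05 with library blocks, and DESeq2 called 17 and 47. The interaction of ID-8 with strain in uncut cultures called 0 as well (220 at an unadjusted p under 0.05, and 30 in DESeq2).

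Within culture sets, without that library, C1ql1 rose in B6 uncut (1.45 ± 0.16, adjusted p = 5.37e-05) and in WSB uncut (1.48 ± 0.16, adjusted p = 0.000109). Its level went from 4.28 ± 1.72 to 11.7 ± 4.02 CPM in B6 and from 29.8 ± 14.1 to 71.9 ± 38.8 CPM in WSB (SD, n = 4, and n = 3 for WSB with ID-8). In B6 uncut the chemokine Cxcl12 (1.02), the lipase Pla2g7 (1.45), the prokineticin receptor Prokr2 (1.67), Ccdc3, Nebl, Tgfb2 (1.05), Dbx2 (1.26), Hopx (1.32), Arhgap36, Ldb2 and Rxfp3 (1.53) rose. The metalloreductase Steap4 (-2.40 ± 0.26), Cdh26, the complement genes C3 (-1.73), C1ra (-1.54) and C1s1 (-1.20), Cd59a (-1.67), Prx, Pcolce (-1.60), ceruloplasmin (Cp, -1.07), Gprc5a and Kcne1l fell. In WSB uncut Scn4b (2.90 ± 0.34), Hopx (1.65), the natriuretic peptide Nppc (2.18), Arhgef37 (2.91), Thrsp (2.68), Aplnr (3.58), Tmem215, Lypd1, Prr5l, Emp2 and Ass1 (1.38) rose. Cp (-1.42 ± 0.20), Nab2 (-1.33), the monocarboxylate transporter Slc16a4 (-2.05), Olfml2a, Prrt1, Gprc5a (-2.61), Slc15a2, Fcgrt, Vcam1 (-1.11), Syndig1l, Vtn (-1.23) and Slc8a2 fell. In cut cultures Nebl (1.27), Pla2g7 (1.53), Prokr2 (1.81), Cxcl12 (1.03), C1ql1 (1.36) and Calcr (2.61) rose and Steap4 (-2.96) and C1ra (-1.95) fell in B6. Ass1 (1.43), Gfra2 (1.19), Scn4b (2.20), Hhip (1.01), C1ql1 (1.07) and Cxcl10 (2.77) rose and C1ra (-1.59) and Vnn1 (-3.72) fell in WSB. Interferon response genes had 5 of 14 higher in WSB cut, 11 adjusted over the list alone, with Oasl2 (1.59), Ifit3 (1.26), Ifi44 (1.19) and Ifit1 (1.96) first (camera, adjusted p = 2.13e-09, and adjusted p = 0.0858 with an estimated correlation). In WSB uncut 5 rose, 7 adjusted over the list alone, with Ifit2 (0.76) first (camera, adjusted p = 0.00169, and 0.968 with an estimated correlation).

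Log2 differences with ID-8 had correlations across genes of 0.55 at the NPC stage, 0.544 at maturation and 0.335 in uncut axon cultures between the strains, and of -0.004 to 0.303 between stages. At the NPC stage 581 genes rose and 531 fell in both strains, against 149.5 and 184.2 for independent lists, and 18 were called in opposite directions. At maturation the shared counts were 295 and 379, against 37.4 and 48.4, with 10 opposite. At the axon stage in uncut cultures, within culture sets and without the library labelled axon WSB ID-8 cut replicate 3, they were 213 and 222, against 21.6 and 24.3, with 0 opposite of 18046 genes tested in edgeR. The log2 differences of B6 at the NPC stage and at maturation had a correlation of -0.004 across 15913 genes, which are not independent replicates, and 540 genes were called in opposite directions, against 552.6 for independent lists. Across all 3 stages and both strains, 10 of 15845 genes fell in all 6 comparisons. These were the complement proteases C1ra and C1s1, Erich3, the activin-binding gene Fstl3, the zinc finger gene Ikzf4, Scube3, Slc16a4, Ssc5d, Tns2 and the matrix gene Vit. In 6 of 6 comparisons 3 genes rose, namely Gnpda1, the checkpoint gene Rad9a and the somatostatin receptor Sstr1. C1ra changed by -1.54 to -2.97, and Sstr1 by 0.57 to 2.82. C1ra and C1s1 share 55.49% and 33.18% of their sampled transcript sequence with other genes, so their values as single genes are uncertain. The axon values in this count came from the fit within culture sets, without the library labelled axon WSB ID-8 cut replicate 3, chosen after seeing the data. With library blocks, 0 genes were called for ID-8 in uncut cultures of either strain, so no gene was called in all 6 comparisons.

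**Figure D4:**
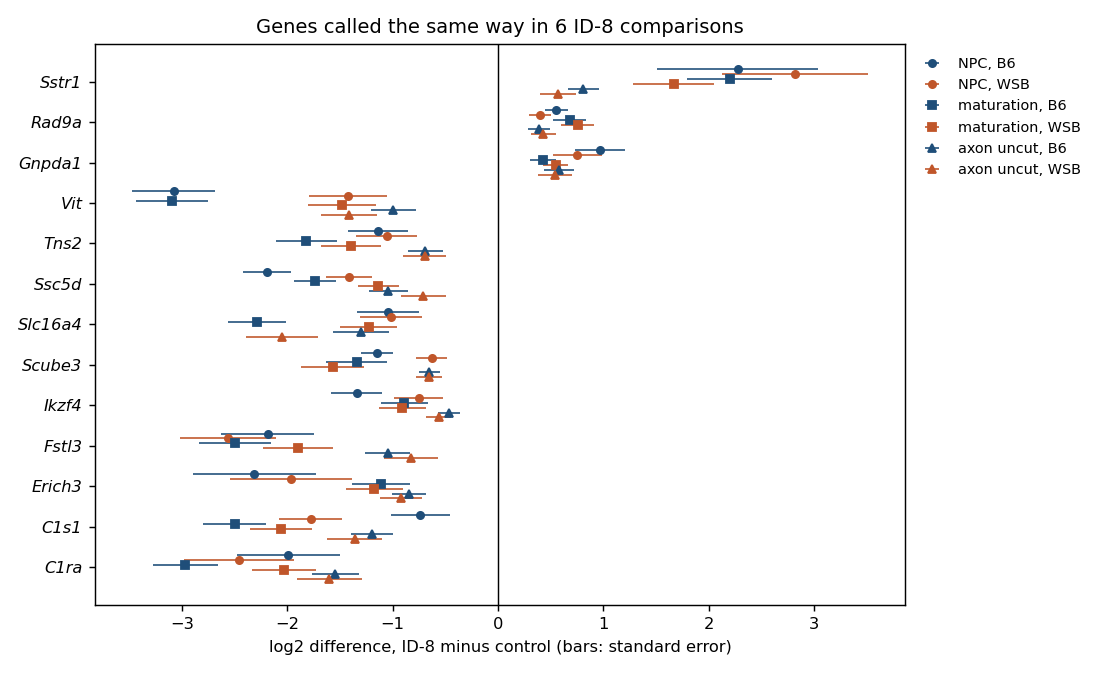
Log2 difference between ID-8 and control, with its standard error as bar, for the 13 genes called in the same direction in 6 comparisons of 3 stages and 2 strains. C1ra fell in every comparison shown, by -1.54 to -2.97. C1ra and C1s1 share 55.49% and 33.18% of their sampled transcript sequence with other genes. Axon values are from the fit within culture sets, without the library labelled axon WSB ID-8 cut replicate 3. With library blocks no gene was called for ID-8 in uncut axon cultures.

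From progenitors to mature neurons, most cell cycle and pluripotency genes were lower and most synaptic, astrocyte and immediate early genes higher in both strains. None of these list calls held with an estimated correlation (adjusted p = 0.481 for each in B6, and 0.543 to 0.563 in WSB). In B6 6487 genes were higher and 6411 lower at maturation, and in WSB 6777 and 6309. The nicotinic receptor modulator Lynx1 rose from 2.22 ± 0.35 to 163.4 ± 9.39 CPM in B6 (SD, n = 6 and n = 4; log2 6.18 ± 0.15, adjusted p = 2.89e-17) and by 6.64 ± 0.15 in WSB. Rasgrf1 (10.02 in B6 and 9.60 in WSB), Mt3, Adra1b, Gas6, Plekhb1 (7.11 and 8.59), Cav2, Fmo2, Folh1 and Smpdl3a rose in both. The neurotrophin Bdnf (4.98) and Sgcb led in B6, and Hr and Tuba4a in WSB. The RNA-binding gene Igf2bp3 fell from 212.8 ± 22.3 to 0.79 ± 0.22 CPM in B6 (-8.11 ± 0.22, adjusted p = 2.29e-16) and by 8.51 ± 0.23 in WSB. Sinhcaf, the lamin Lmnb1 (-5.68 and -5.56), Racgap1, Mex3a, Mycl and Rcor2 fell in both. Lin28a (-11.27), Mycn (-6.84), Jarid2 and Zc3hav1l led in B6, and Tgfbr1, Epb41, Bzw2 and Usp3 in WSB. In B6 23 of 24 cell cycle genes fell and 1 rose, 23 and 1 adjusted over the list alone, with Aurkb (-7.43), Mcm6 (-4.97), Aurka (-6.44) and Cdk1 (-6.91) first (camera, adjusted p = 1.99e-11, and 0.481 with an estimated correlation), and in WSB 22 fell and 1 rose, 22 and 1 adjusted over the list alone (camera, adjusted p = 8.06e-10, and 0.543 with an estimated correlation). Synaptic genes had 15 of 18 higher in B6, 15 adjusted over the list alone, with Syp (3.48), Cplx1 (4.55), Camk2a (2.09) and Syn2 (3.51) first (camera, adjusted p = 1.18e-05, and 0.481 with an estimated correlation), and in WSB 13 were higher and 1 lower, 13 and 1 adjusted over the list alone (camera, adjusted p = 0.00235, and 0.563 with an estimated correlation). Immediate early genes had 12 of 13 higher in both strains, 12 adjusted over the list alone, with Fos at 3.52 and 4.43 and Egr1 at 3.78 and 4.64 (camera, adjusted p = 0.00165 in B6 and 0.000661 in WSB, and 0.481 and 0.543 with an estimated correlation). Dcx, a gene of young neurons, fell by 6.08 in B6 and 7.00 in WSB. Pluripotency genes had 14 of 15 lower in B6, and 12 lower and 1 higher in WSB, 14, 12 and 2 adjusted over the list alone (camera, adjusted p = 2.1e-08 and 0.000584, and 0.481 and 0.543 with an estimated correlation). Astrocyte genes had 9 of 10 higher in B6, and 8 higher and 1 lower in WSB, 9, 8 and 1 adjusted over the list alone (camera, adjusted p = 0.000902 and 0.00283, and 0.481 and 0.543 with an estimated correlation). The stages came from different library blocks.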

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

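Of the tests reported in this part, those of the library labelled axon WSB ID-8 cut replicate 3, of shared reads at maturation and at the axon stage, of reads shared with a pseudogene called higher, of the strain calls as a whole, of the interferon response at the axon stage, and of swaps within culture sets were chosen after the result was seen. Of 70 tests of a group of libraries on 1 of 5 measures, 5 found a single library far from the rest of its group, where chance gives about 1 in 20. The total of axon WSB control cut replicate 2 was 99.19 in units of 1e6 counts, against 33.41 for the next. NPC B6 control replicate 2 had 1.661% of its counts in pseudogenes, against 1.341% for the next. Maturation B6 ID-8 replicate 1 had 1.003% in pseudogenes, against 0.7913%. The strain index of maturation B6 control replicate 4 was -0.4616, against -1.217. Axon WSB control uncut replicate 4 had 11.93% of its counts in mitochondrially encoded genes, against 4.753%. A test of the difference between the strains' responses to ID-8 called 551 genes at the NPC stage and 78 at maturation, and the median difference of the interferon response list at maturation was 2.544.

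In the strain comparisons pseudogenes were called higher in WSB and their parent genes lower. Of 518 pseudogenes at the NPC stage 154 were higher and 90 lower. Of 428 at maturation 129 were higher and 39 lower, and of 597 at the axon stage 128 and 37. If shared reads had been assigned to different genes in the strains, sums over the sharing genes should lie near 0, and over 389 lower genes with shared sequence at the NPC stage the median went from -1.994 for the genes alone to -1.656 summed, over 129 at maturation from -2.138 to -0.778 and over 174 at the axon stage from -2.253 to -1.289, but only 46, 32 and 27 of these genes share with a pseudogene called higher, so these medians decide nothing about the pattern. For the 46 NPC genes that share sequence with a pseudogene called higher the median went from -2.05 alone to -0.526 summed. For the 32 such genes at maturation it went from -2.68 to -0.023, and for the 27 at the axon stage from -2.629 to -0.038. These genes were picked on both calls, which pulls sums toward 0. Over 394 NPC genes that share with any tested pseudogene, called or not, the median size went from 0.395 to 0.327. Over 337 such genes at maturation it went from 0.412 to 0.263, and over 417 at the axon stage from 0.394 to 0.2. Sums thus lay nearer 0 at each stage, and how far shared reads account for the pattern stays open. Shared sequence did not account for the strain calls as a whole, since genes without it were called at no less than 0.795 times the rate of other genes. A true difference in expression and a difference in how the 2 strains' reads were mapped both stay open, since no reads were at hand.

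The library labelled axon WSB ID-8 cut replicate 3 had a strain index of -1.333, inside the range of the 15 B6 libraries of the stage (-1.815 to 0.074) and outside that of the other 14 WSB libraries (1.472 to 2.816), and as the index sets 1 higher gene against 90 lower ones, the mean level of the 90 alone was compared too and read 1.333, against 1.142 to 1.815 in B6 and 0.596 to 0.842 in WSB. A mixture of both strains in similar parts would lie between the ranges, which -1.333 does not. A WSB library quantified as the B6 libraries were should still resemble its own culture set over genes that did not differ by strain. Such genes were picked at the NPC stage, so strain differences of the axon stage can remain among them. Over these 2329 genes the library's highest correlation with its own culture set was -0.259, against 0.845 with axon B6 ID-8 uncut replicate 2. The next highest values were 0.576 and 0.541, with the control cut and control uncut libraries of the same B6 culture set. The best match itself set the upper end of the B6 range of the strain index, at 0.074, above the other libraries of its set. Why it did so was not tested. A wrong label on a B6 library could explain the strain index and these correlations, and the B6 culture set of that best match has no ID-8 cut library. No genotype was at hand, so this stays a hypothesis.

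Interferon response genes moved apart between the strains with ID-8 at maturation. The difference was not carried by 1 culture experiment, as the list medians were 2.662 and 2.531 in the 2 experiments, nor by shared sequence, as the median over the 8 members without it was 3.16. If the strains differ in their interferon response to ID-8, the axon stage should show it too, and the lower of its 2 medians was 0.79 (uncut, 13 of 14 members above 0 and 0 called, within culture sets and without the library labelled axon WSB ID-8 cut replicate 3), with 1.424 in cut cultures, but the list's mean log2(CPM + 1) in uncut cultures went from 1.606 to 1.958 with ID-8 in WSB and from 2.662 to 2.607 in B6, so the fall seen in B6 at maturation (3.679 to 2.563) did not recur there. At the NPC stage the list leaned downward with ID-8 in both strains, at medians of -1.296 in B6 and -0.527 in WSB, and the median of their difference was 0.649 with 0 of 13 members called. As a hypothesis, ID-8 could act on this response differently in the strains, and an infection or a change of cell composition within 1 strain's treated cultures was not tested.

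Other splits of the same libraries were fitted to see how often they called as many genes as the real one. The limit set for each count was a share of splits under 0.05, with no correction over the counts. A share under it therefore does not exclude chance. At the NPC stage 1 of 40 splits, the real one, gave as many genes for strain (real 7763, highest other 5318), for ID-8 in B6 (6968 and 2763) and for ID-8 in WSB (1650 and 208), a share under 0.05 for each. These highest other splits exchanged the labels of 10, 8 and 10 libraries from groups of 6, so they still held the real groups largely apart. The median count over the other splits was 0 for each. For the NPC interaction 2 of 40 splits gave as many (551 and 1859), a share not under 0.05. At maturation 1 of 35 splits gave as many for ID-8 in WSB (999 and 600), a share under 0.05. For strain 2 of 35 did (2505 and 2807), for ID-8 in B6 2 of 35 (2902 and 4198), and for the interaction 2 of 40 (78 and 2843). The highest other splits for strain and for ID-8 in B6 put whole culture experiments against each other, and with the experiment as a block the counts were 4608 and 4823. The split that called 2843 genes for the interaction divided the culture experiments, what structure of the samples it follows was not tested, and the count with the experiment as a block was 323. The share was under 0.05 for strain at the axon stage (1 of 35 splits, 2397 and 0) and for maturation against NPC (1 of 40 splits in each strain, 12898 and 7336 in B6, 13086 and 7775 in WSB). For maturation against NPC the highest other splits relabelled 8 libraries in each strain, so most labels were exchanged. The median count over the other splits was 0 there too.

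For the 10 axon counts of 0 from edgeR, all 24 of 24 splits gave as many, as any split must, so these splits decide nothing. The highest other splits called 1563 genes for axotomy in B6, 922 for ID-8 in B6 cut cultures, 2791 for ID-8 in WSB cut cultures and 88 for ID-8 by axotomy in WSB. Those of 2791 and 88 divided culture sets, and what structure of the samples they follow was not tested. Those of 1563 and 922 put whole culture sets against each other, and with culture sets as a block the counts for axotomy and for ID-8 in cut cultures of B6 were 0 and 275 (1556 and 2085 at an unadjusted p under 0.05). The highest others were 0 for axotomy in WSB, 0 for strain by axotomy, 0 for ID-8 in B6 uncut, 1 for ID-8 in WSB uncut, 1 for strain by ID-8 and 0 for ID-8 by axotomy in B6. At an unadjusted p under 0.05 the real counts were 182, 717, 137, 751, 1322, 220, 675, 1380, 65 and 742, and DESeq2 called 31, 23, 36, 74, 87, 30, 29, 121, 17 and 47, for axotomy in B6 and WSB, strain by axotomy, ID-8 uncut in B6 and WSB, strain by ID-8, ID-8 cut in B6 and WSB, and ID-8 by axotomy in B6 and WSB. Swaps within culture sets, without the library labelled axon WSB ID-8 cut replicate 3, made too few splits for a share under 0.05. The real and highest other counts were 1 and 1 for axotomy in B6 (4 of 8 splits as large), 272 and 0 in WSB (1 of 8), 818 and 4 for ID-8 in B6 uncut (1 of 8), 2028 and 0 in WSB uncut (1 of 4), 743 and 0 in B6 cut (1 of 4), and 313 and 0 in WSB cut (1 of 4).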

How the results depend on the processing

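Fits with culture sets or experiments, on genes without shared sequence, or without the library labelled axon WSB ID-8 cut replicate 3 were chosen after seeing the data, and the other alternatives were not. No named gene reversed its direction under any alternative. Of the counts of calls under other settings, 252 stayed within 1.5 times and 76 moved further, and for these the cause was not tested except where fewer libraries or genes were fitted. RLE size factors, no filter and first runs moved no count above 0 by over 1.5 times. Of the named genes' values under the first set of alternatives 15437 kept their side of the threshold and 2290 lost it, and under the later ones 1776 kept it, 90 lost it and 1 gained it. The median log2 difference moved by at most 0.059 under any setting. A pseudocount was not varied, because the values were counts.

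At the NPC stage the first and second library blocks alone, with fewer libraries, gave 4213 and 2794 genes for strain, 1379 and 3880 for ID-8 in B6, and 166 and 2 for ID-8 in WSB. For the interaction edgeR gave 0 and 0 (1292 and 2526 at an unadjusted p under 0.05), 254 with no library block term and 1748 with culture sets as a block, and DESeq2 gave 1251. With replicate numbers as a block, in the first library block, the counts were 5295 for strain, 2010 for ID-8 in B6, 284 in WSB and 1 for the interaction. Within WSB 3 of 3 pairs of 1 number correlated above 0.1 (lowest 0.326), within B6 2 of 3 did (lowest 0.068), and over all 4 groups 13 of 18 (median 0.276, lowest -0.147). Genes without shared sequence, fewer in number, gave 4588 for strain, 1345 at maturation and 1277 at the axon stage.

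At maturation, with the culture experiment as a block, the counts were 4608 for strain, 4823 for ID-8 in B6, 2407 for ID-8 in WSB and 323 for the interaction. The first experiment alone gave 4821, 5414, 2329 and 484, and the second 4998, 5068, 2625 and 611. DESeq2 called 1772 for ID-8 in WSB and 327 for the interaction.

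At the axon stage strain gave 1590 with no library block term. Where edgeR called 0, DESeq2 called 31 for axotomy in B6 (182 at an unadjusted p under 0.05), 23 in WSB (717), 36 for strain by axotomy (137), 74 for ID-8 uncut in B6 (751), 87 in WSB (1322), 30 for strain by ID-8 (220), 29 for ID-8 cut in B6 (675), 121 in WSB (1380), and 17 and 47 for ID-8 by axotomy in B6 (65) and WSB (742). With culture sets as a block, and then also without the library labelled axon WSB ID-8 cut replicate 3, counts were 0 (1556 unadjusted) and 1 for axotomy in B6, 1 and 272 in WSB, 221 and 818 for ID-8 uncut in B6, 563 and 2028 in WSB, 275 and 743 for ID-8 cut in B6, and 357 and 313 in WSB. Without that library and with library blocks ID-8 uncut in B6 gave 1. RLE size factors gave 1 for ID-8 cut in B6, and first runs gave 4 for ID-8 uncut and 1 for ID-8 cut in WSB.

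Leaving out each replicate of the groups compared gave 1798 to 2122 for strain at maturation, 2122 to 2796 for ID-8 in B6 and 511 to 997 in WSB. In WSB the counts were 511, 577 and 639 without control replicates 1, 2 and 3, and 623 and 565 without ID-8 replicates 2 and 4. The maturation interaction ran from 40 to 142, with 40 and 46 without WSB control replicates 3 and 4, 44 without B6 control replicate 4, 50 without B6 ID-8 replicate 4, and 45 and 142 without WSB ID-8 replicates 2 and 3. Strain at the axon stage ran from 1404 to 2966, with 1518 and 1404 without WSB control uncut replicates 2 and 3. The ranges were 0 to 0 for axotomy in B6, 0 to 2 in WSB (2 without control cut replicate 1), 0 to 1 for ID-8 uncut in B6 (1 without axon WSB ID-8 cut replicate 3) and in WSB (1 without control uncut replicate 1), and 0 to 1 for ID-8 cut in B6 (1 without control cut replicate 1). For ID-8 cut in WSB the range was 0 to 12, with 7 and 12 without ID-8 cut replicates 1 and 2 and 3 without control cut replicate 3. All 4 axon interactions stayed at 0 to 0. Without each of the 4 maturation libraries, stage gave 12483 to 12657 in B6 and 12581 to 12781 in WSB, and no NPC library was left out of any fit. Of 153 list calls with the preset correlation, 0 held with an estimated correlation.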

Other observations

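The values of single libraries in this part were looked at after the strain comparisons had been seen. From progenitors to mature neurons, further gene lists were called in both strains, though not with an estimated correlation (adjusted p = 0.214 to 0.543). Cholesterol synthesis had 14 of 16 genes lower and 2 higher in B6 and 14 lower in WSB, with the same numbers adjusted over the list alone, with Dhcr7 (-2.04 and -2.24) and Srebf2 (-1.82 and -2.06) among them (camera, adjusted p = 0.00178 and 0.000203, and 0.489 and 0.543 with an estimated correlation). Proneural genes had 10 of 13 lower in each strain and 1 higher in B6, with the same numbers adjusted over the list alone, with the Notch ligand Dll1 (-5.73 and -5.86) and the neurogenic factor Neurog2 (-8.38 and -7.58) first (camera, adjusted p = 8.19e-05 and 6.23e-05, and 0.274 and 0.214 with an estimated correlation). Of 21 Hox genes 15 were lower and 1 higher in each strain, 15 and 1 adjusted over the list alone, among them Hoxc5 (-3.46 and -3.42) and Hoxd3 (-2.57 and -3.48) (camera, adjusted p = 0.000589 and 0.000661, and 0.481 and 0.543 with an estimated correlation). All 13 mitochondrially encoded genes were higher in each strain, 13 and 13 adjusted over the list alone, such as mt-Nd2 (2.33 and 2.04) (camera, adjusted p = 3.82e-05 and 6.23e-05, and 0.481 and 0.543 with an estimated correlation).

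In B6 progenitors with ID-8, of 8 genes of the kinase family of its target 5 were lower and 1 higher, 5 and 1 adjusted over the list alone, and the list as a whole did not pass (camera, adjusted p = 0.132). Dyrk2 (-0.68), Dyrk1b (-0.86), Clk3 (-0.27) and Clk4 (-0.32) were lower and Dyrk3 (0.32) higher, with Clk1 (-0.09, adjusted p = 0.667) and Clk2 (0.02, adjusted p = 0.872) short of the threshold. Clk1 to Clk4, Hes1 and Hey2 were chosen for naming after their values were seen. Notch targets had 6 of 8 lower and 2 higher, 6 and 2 adjusted over the list alone, with Hes5 (-2.62), Heyl (-1.92) and Hey1 (-2.16) lower and Hes1 (0.48) and Hey2 (0.79) higher (camera, adjusted p = 0.0602).

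The 4 WSB axon libraries of 1 culture set differed from the other WSB axon libraries in genes with pseudogene copies. They were also the only axon libraries of their library block, so culture set and library block cannot be told apart here. Axon WSB control uncut replicate 4, ID-8 uncut replicate 3, control cut replicate 4 and ID-8 cut replicate 4 had 667.5, 596.15, 397.64 and 299.41 CPM of Gapdh, and 54.64, 59.26, 46.51 and 53.07 CPM of Rps2. The other libraries labelled WSB at that stage, apart from ID-8 cut replicate 3 with 1157.93 CPM of Gapdh and 904.33 of Rps2, had 28.64 to 75.54 CPM of Gapdh and 4.01 to 8.4 of Rps2. The strain index of axon B6 ID-8 uncut replicate 2 was 0.074, and the other B6 libraries of its set read -1.142 (control uncut replicate 2) and -1.18 (control cut replicate 2).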
